A study of Rattus norvegicus with 4 samples.

How the data were processed

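Total RNA of rat primary chondrocytes, untreated (0 h) or treated with 10 ng/ml IL-1β for 6, 12 or 24 h, had been profiled on 4 miRNA arrays, 1 per group. Per the labels, the authors extracted total RNA with a column kit, kept the small RNAs by filtration, added a poly(A) tail to their 3′ ends and ligated a tag to the tail that was later stained with Cy5. The deposited file of each array holds the mean intensity of 3968 spots, in linear scanner units. The values of the 261 empty spots showed that no background had been subtracted. A table by the authors gives 1 intensity per array for the same 679 miRNAs, on a linear scale; its lowest value of 0 and its like medians on the 4 arrays (24.3, 22.5, 23.4 and 20.3) are those of values with background removed and arrays on a common scale, by a method that the sources used here do not give. It correlated with the spot intensities across miRNAs at r = 0.997, 1.000, 0.999 and 1.000 for the control, 6, 12 and 24 h. The scanner and image software are likewise not given there.

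Each array carries 5 spots for each of 679 rat miRNA probes, named here without the rat prefix, together with the empty spots, 20 spots named as background, 24 of 5S RNA and 268 of spike calibration. The 5 spots of a probe are repeats on 1 array of 1 sample, not biological replicates. Spot intensities were corrected for background with the normexp method of limma 3.58.1 in R 4.3.3 (offset 50, with the spots' own intensities since no local background column is given), brought to a common distribution by quantile normalization over the miRNA spots, put on the log2 scale and averaged over a probe's 5 spots. Further steps used Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3, and the plots matplotlib 3.10.9. A spot counted as signal above the 95th percentile of the array's empty spots, and a miRNA was detected where at least 3 of its 5 spots did. That limit was 151.3 units in the control and 54.2, 96.4 and 86.2 at 6, 12 and 24 h. Total miRNA spot intensity was 2.95e+06, 3.57e+06, 4.71e+06 and 4.19e+06 units in that order, and the brightest spots read between 48618 and 63062.

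Each treated array was compared with the control, and the treated arrays with the next time point, over miRNAs detected on at least 1 of the arrays compared. With 1 array per group no test across conditions is possible and no p-value was computed. The standard error of a change came from the 5 spots on each array. A miRNA counted as changed where its log2 change was at least 1 and larger than 2 times that error. Where an array did not detect the miRNA, its level there was set to the lowest log2 level of a miRNA detected on that array (6.89 in the control and 6.31, 6.60 and 6.77 at 6, 12 and 24 h), or to its own if higher, and the fold was written as a bound; the call itself used the measured level, so a bound may be under 2-fold. The miRNAs named are the up to 12 largest changes each way per treatment comparison among those changed and detected on both arrays, the up to 6 brightest given as bounds, the 5 largest each way between treated arrays, those changed one way at all 3 times, and members of the fixed lists; any other is said to be chosen after its values were seen.

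Fixed lists held inflammation-induced, chondrocyte-enriched and mesenchymal miRNAs, regulators of cartilage matrix and proteases, and the let-7, miR-17-92, miR-29, miR-30, miR-15/16, miR-23/27/24, miR-181 and miR-34 families, 12 lists in all; 6 further lists held markers of blood, epithelial, endothelial, muscle, neural and liver cells. A listed miRNA with no probe of its name, such as miR-155, did not enter. The median change of a list was placed among 10000 random lists of the same size matched on level in 5 bins, as a description of these arrays, and stood apart below the 2.5th or above the 97.5th percentile. For changes at all 3 times, 1000 simulations drew unchanged treated arrays against 1 shared control, with noise at like level taken from the spread among the 3 treated arrays, since no replicate gives it. On simulated data, in which the control array was set against itself with spot noise alone and 60 of 679 miRNAs changed, the rule recovered 0 of 20 changes of 1.5-fold, 1 of 20 of 2-fold and 16 of 20 of 4-fold, and called 0 of 619 unchanged ones. The median absolute log2 change measured for these true folds was 0.46, 0.77 and 1.66. Folds thus came out smaller than those put in, and the rule of 2-fold asked for a larger true change.

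The comparisons, the rules, the lists and the first set of alternatives were fixed before the data were examined. Those alternatives were plain subtraction of the empty-spot median, no background correction, cyclic loess, scaling to the median of miRNAs detected on all 4 arrays, no normalization between arrays, the authors' values (with 50 added before log2 and no spot error), detection on both arrays, no filter, an offset of 16, the median of spots, a 1.5-fold rule, no spot-error rule and, for detection, all 5 spots. Chosen after seeing the data were a linear correction for GC content, normalization without the 12 h array, leaving out probes within 4 edits of a probe at least 4 times brighter, unnormalised changes centred on their median, and undetected levels set to the lowest detected level. Genome positions of the miRNAs are not used here.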

Results

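MicroRNA (miRNA) levels were measured in rat primary chondrocytes, the cells that make and maintain cartilage matrix. The cells were cultured at 200000 per ml and left untreated (0 h, the control) or treated with 10 ng/ml interleukin-1β (IL-1β), an inflammatory cytokine, for 6, 12 or 24 h. Each of the 4 groups was 1 sample on 1 array of 679 rat miRNA probes, with 5 spots per probe. No group had a replicate array, so no difference between groups could be set against a spread between samples. The only untreated array is that of 0 h, with none at 6, 12 or 24 h. An effect of IL-1β can therefore not be told apart from one of time in culture in any change from the control. Each ± is the standard error from the repeat spots of the arrays compared, which covers spot-to-spot error only. The number of arrays limits the precision. Signal above the empty spots was found for 187 miRNAs in the control and for 355, 240 and 210 at 6, 12 and 24 h. Of the 679, 163 were detected on all 4 arrays and 322 on none. The median signal of the empty spots was 122.6 units in the control and 46.2, 75.3 and 65.0 at 6, 12 and 24 h. The dimmest signal that could be seen therefore differed between arrays. Detected miRNAs had a median spot-to-spot coefficient of variation of 11.3% in the control and 11.9%, 9.84% and 9.54% at the 3 treated times. Between arrays, the log2 levels of the 357 miRNAs detected at least once were closest for 6 h and 12 h (r = 0.992 across miRNAs, which are not independent replicates) and farthest apart for the control and 24 h (r = 0.962).

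A miRNA rose or fell where its log2 change was at least 1 (2-fold) and more than 2 times its spot standard error, on the quantile-normalised scale. Where an array did not detect it, the call used its measured level there, below detection, and the fold is given as a bound that may lie under 2-fold. With undetected levels set to the lowest detected level, an alternative chosen after seeing the data, 3 rose and 8 fell at 6 h, 12 and 10 at 12 h, and 13 and 11 at 24 h. Some other scalings shifted the changes as a whole. Scaling to the median of the miRNAs detected on all 4 arrays put the median change at -0.45, -0.34 and -0.34 at 6, 12 and 24 h, and leaving out normalization put it at -0.32, 0.40 and 0.30, against 0.03, 0.09 and 0.02 on the quantile scale. The changes also ran with the GC content of the miRNA (r = -0.43, -0.47 and -0.44 across miRNAs at 6, 12 and 24 h). Changes were lower for GC-rich sequences, as the plot of change against GC content shows.

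After 6 h of IL-1β, 13 of the 355 miRNAs compared had changed, 5 higher and 8 lower than in untreated chondrocytes. The largest rise was that of miR-365, at 3.35-fold (log2 1.75 ± 0.23). miR-29c, of a family whose known targets include collagen transcripts, rose 2.27-fold (1.18 ± 0.23), and miR-10b, which is encoded within a Hox gene cluster, rose 2.06-fold (1.04 ± 0.10). The largest falls were those of miR-290, of a cluster best known from rodent embryonic stem cells, at 4.64-fold (-2.21 ± 0.17), and of miR-365*, the opposite arm of the miR-365 hairpin, at 4.54-fold (-2.18 ± 0.11). Lower too were miR-1249 (3.60-fold, -1.85 ± 0.26), miR-377 (2.92-fold, -1.55 ± 0.73) and miR-3593-3p (2.61-fold, -1.39 ± 0.19). Smaller falls were those of miR-3573-3p (2.58-fold, -1.37 ± 0.21), miR-672 (2.11-fold, -1.08 ± 0.13) and miR-455* (2.07-fold, -1.05 ± 0.08). miR-221* and miR-322 were detected at 6 h and not in the control, at least 1.61-fold and at least 1.40-fold higher, so that neither reached 2-fold as a bound. miR-146a, which NF-κB signalling induces, had a log2 change of 0.97 ± 0.13, under the rule on the quantile scale and past it without normalization and after centring. The split of 5 higher and 8 lower became 9 and 26 after median scaling, 14 and 11 without normalization, 22 and 5 when the unnormalised changes were centred on their median, 3 and 8 among miRNAs seen on both arrays, 2 and 7 without the 12 h array in the normalization, and 2 and 8 after a correction for GC content. The calls of miR-10b, miR-29c, miR-221*, miR-322, miR-377, miR-455* and miR-672 ended under at least 1 other processing, with miR-29c at 0.87 after GC correction, whereas miR-365, miR-365*, miR-290, miR-1249, miR-3573-3p and miR-3593-3p passed under every one tried.

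After 12 h, 24 of 249 miRNAs had changed, 14 higher and 10 lower. miR-29c stood 6.36-fold above the control (log2 2.67 ± 0.19) and its relative miR-29b 2.89-fold (1.53 ± 0.17). miR-98, a let-7 family member, rose 6.32-fold (2.66 ± 0.28) and let-7e 2.25-fold (1.17 ± 0.14). The inflammation-responsive miR-146a rose 2.62-fold (1.39 ± 0.10), and miR-365 stayed high at 5.17-fold (2.37 ± 0.16). miR-290 had fallen 8.31-fold (-3.06 ± 0.14) and miR-365* 4.64-fold (-2.21 ± 0.12). Also higher were miR-494 (4.66-fold, 2.22 ± 0.15), miR-466d (2.42-fold, 1.27 ± 0.25) and miR-328a* (2.30-fold, 1.20 ± 0.32). Rises nearer to 2-fold were those of miR-350 (2.15-fold, 1.11 ± 0.20), miR-352 (2.11-fold, 1.08 ± 0.16) and miR-148b-3p (2.00-fold, 1.0 ± 0.15). The lower miRNAs included miR-3573-3p (4.83-fold, -2.27 ± 0.18), miR-3593-3p (3.29-fold, -1.72 ± 0.14) and miR-672 (3.07-fold, -1.62 ± 0.14). They also included miR-455* (2.61-fold, -1.39 ± 0.08), miR-1224 (2.51-fold, -1.33 ± 0.04) and miR-3584-5p (2.17-fold, -1.12 ± 0.24). Seen on 1 of the arrays only, miR-20b-5p and miR-322 were at least 1.89-fold and at least 1.88-fold higher, both under 2-fold as bounds. miR-1249 and miR-296* were at least 7.47-fold and at least 2.73-fold lower.

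Of the control probes whose names read as mismatched versions, 10 were above the empty spots on all 4 arrays, with 8 matched partners. Their median signal at 12 h was 23.3% of the matched signal, against 2.23% in the control, 3.22% at 6 h and 1.96% at 24 h. Other probes so named did not enter. Some stayed near background at 12 h, such as Ctr01-3M05, at 4.62 units net of the empty spots beside 22971 for Ctr01-3P. Ctr04-3M05 read 11.4 units net at 12 h, under its 25.0 at 6 h and 97.4 at 24 h. Ctr07-3M05 and Ctr07-3M10, which rose most, had 4 uneven spots each at 12 h (means of 9094 and 10930 units, SD 3954 and 5063). Pair by pair, the median ratio of 12 h to the other arrays was smaller, at 3.05 over the control, 2.96 over 6 h and 4.52 over 24 h. Probes within 4 edits of a probe at least 4 times brighter read higher at 12 h than on the mean of the 6 h and 24 h arrays, with a median excess of 0.23 over 18 probes, against -0.03 for the other 339. Brightness was judged on the control, 6 h and 24 h arrays, so choosing dimmer probes there can itself favour an excess at 12 h. Of the 14 miRNAs that rose at 12 h, 8 were left without such related probes, beside 10 that fell. miR-98, miR-29b, miR-29c and miR-352 were among those removed. The split of 14 higher and 10 lower became 14 and 28 after median scaling, 52 and 6 without normalization, 26 and 16 after centring and 9 and 10 after GC correction. The calls of miR-29c, miR-98, miR-365, miR-494, miR-146a, miR-290, miR-365*, miR-3573-3p and miR-3593-3p held under every scaling and correction, those of miR-29b (0.94) and let-7e (0.79) ended after GC correction, that of miR-328a* ended in the authors' values (0.76) and with the median of spots (0.79), and miR-3584-5p read 0.14 without normalization and -0.26 after centring. Calls also ended in at least 1 setting for miR-1224 (to -0.06), miR-455* (to -0.12), miR-672 (to -0.60), miR-296* (to -0.96), miR-148b-3p (to 0.57), miR-20b-5p (to 0.47), miR-466d (to 0.58), miR-352 (to 0.60), miR-322 (to 0.71) and miR-350 (to 0.75), and that of miR-1249 where detection on both arrays was required.

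**Figure D1:**
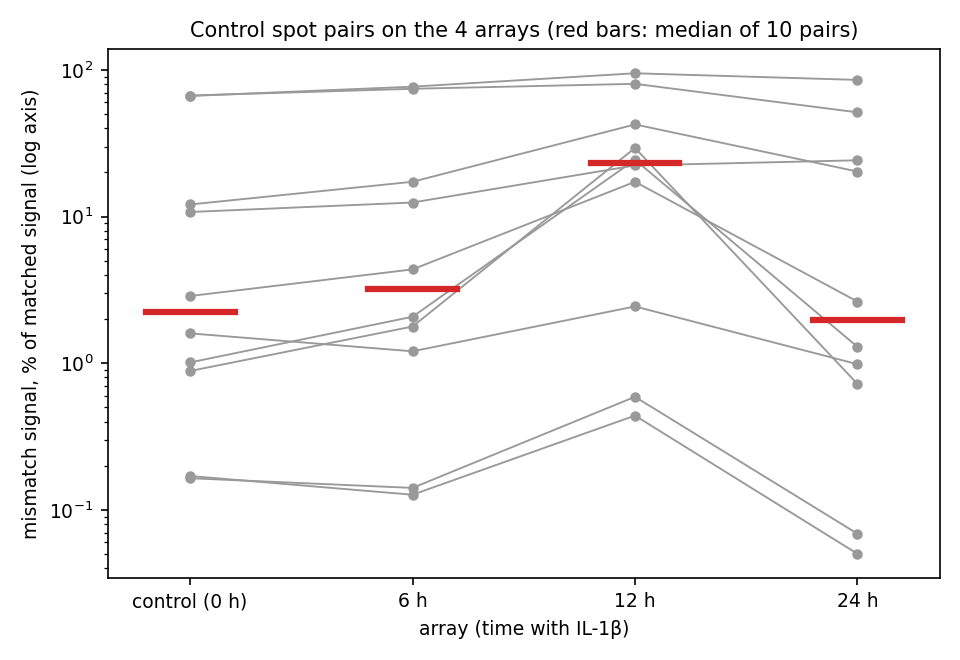
Signal of mismatch-named control spots as a percentage of their matched partners (y axis, log scale) on the control, 6, 12 and 24 h arrays. Each grey line joins 1 of 10 pairs, and the red bars are the medians. Only mismatched probes above the empty spots on every array are shown. Other probes so named, some of them near background at 12 h, are left out. The median was 23.3% at 12 h and between 1.96% and 3.22% on the other arrays, while the median ratio within pairs was 2.96 to 4.52.

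After 24 h, 32 of 233 miRNAs had changed, 19 higher and 13 lower. miR-146a rose further, to 5.74-fold (log2 2.52 ± 0.13), and miR-29b and miR-29c stood 5.03-fold (2.33 ± 0.21) and 3.62-fold (1.85 ± 0.27) above the control. miR-101a and miR-101b, whose known targets include the histone methyltransferase Ezh2, rose 4.29-fold (2.10 ± 0.09) and 3.35-fold (1.74 ± 0.10). Whether their probes read separate signals was not examined. Some members of the growth-promoting miR-17-92 cluster rose as well: miR-20a 2.88-fold (1.53 ± 0.06), miR-19b 2.61-fold (1.39 ± 0.14) and miR-17-5p 2.08-fold (1.06 ± 0.07). Of the others compared, miR-18a was at 0.88 without passing and miR-92a was at -0.014. The cartilage-enriched miR-140 rose 2.58-fold (1.37 ± 0.10). miR-494 stood 5.20-fold higher (2.38 ± 0.11). The largest fall was that of miR-328a*, at 11.6-fold (-3.54 ± 0.37), ahead of miR-329 (5.06-fold, -2.34 ± 0.13). Next came miR-672 (3.10-fold, -1.63 ± 0.12), miR-365* (3.0-fold, -1.59 ± 0.12) and miR-3584-5p (2.70-fold, -1.44 ± 0.24). Falls closer to 2-fold were those of miR-296* (2.41-fold, -1.27 ± 0.21), miR-34c* (2.32-fold, -1.21 ± 0.08) and miR-98 (2.28-fold, -1.19 ± 0.21). Bounds were given by miR-31*, miR-3588 and miR-20b-5p, at least 2.84-fold, 2.63-fold and 2.26-fold higher. On the other side, miR-1249, miR-377 and miR-3573-3p were at least 6.80-fold, 4.67-fold and 4.57-fold lower. miR-290, given here because it was lower at the earlier times, had a log2 change of -0.23 ± 0.19 at 24 h. The median GC content was 40.9% in the miRNAs that rose, 61.9% in those that fell and 50% in the rest. The split of 19 and 13 became 12 and 13 after GC correction, 9 and 44 after median scaling and 19 and 31 after centring, and 34 and 18 without normalization and 22 and 14 in the authors' values. Among detections on both arrays, 10 rose and 8 fell. The calls of miR-146a, miR-29b, miR-29c, miR-101a, miR-101b, miR-20a, miR-494, miR-328a* and miR-329 held under every scaling and correction tried. Those of miR-140 (0.83) and the bounds of miR-20b-5p, miR-31* and miR-3588 ended after median scaling, and that of miR-19b (0.95) after GC correction. The call of miR-17-5p ended in 4 settings (to 0.93), among them loess (0.97). Falls that ended in at least 1 setting were those of miR-3584-5p (to -0.48), miR-34c* (to -0.50), miR-98 (to -0.71), miR-296* (to -0.73), miR-672 (to -0.83) and miR-365* (to -0.95), and those of miR-1249, miR-377 and miR-3573-3p where detection on both arrays was required.

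**Figure D2:**
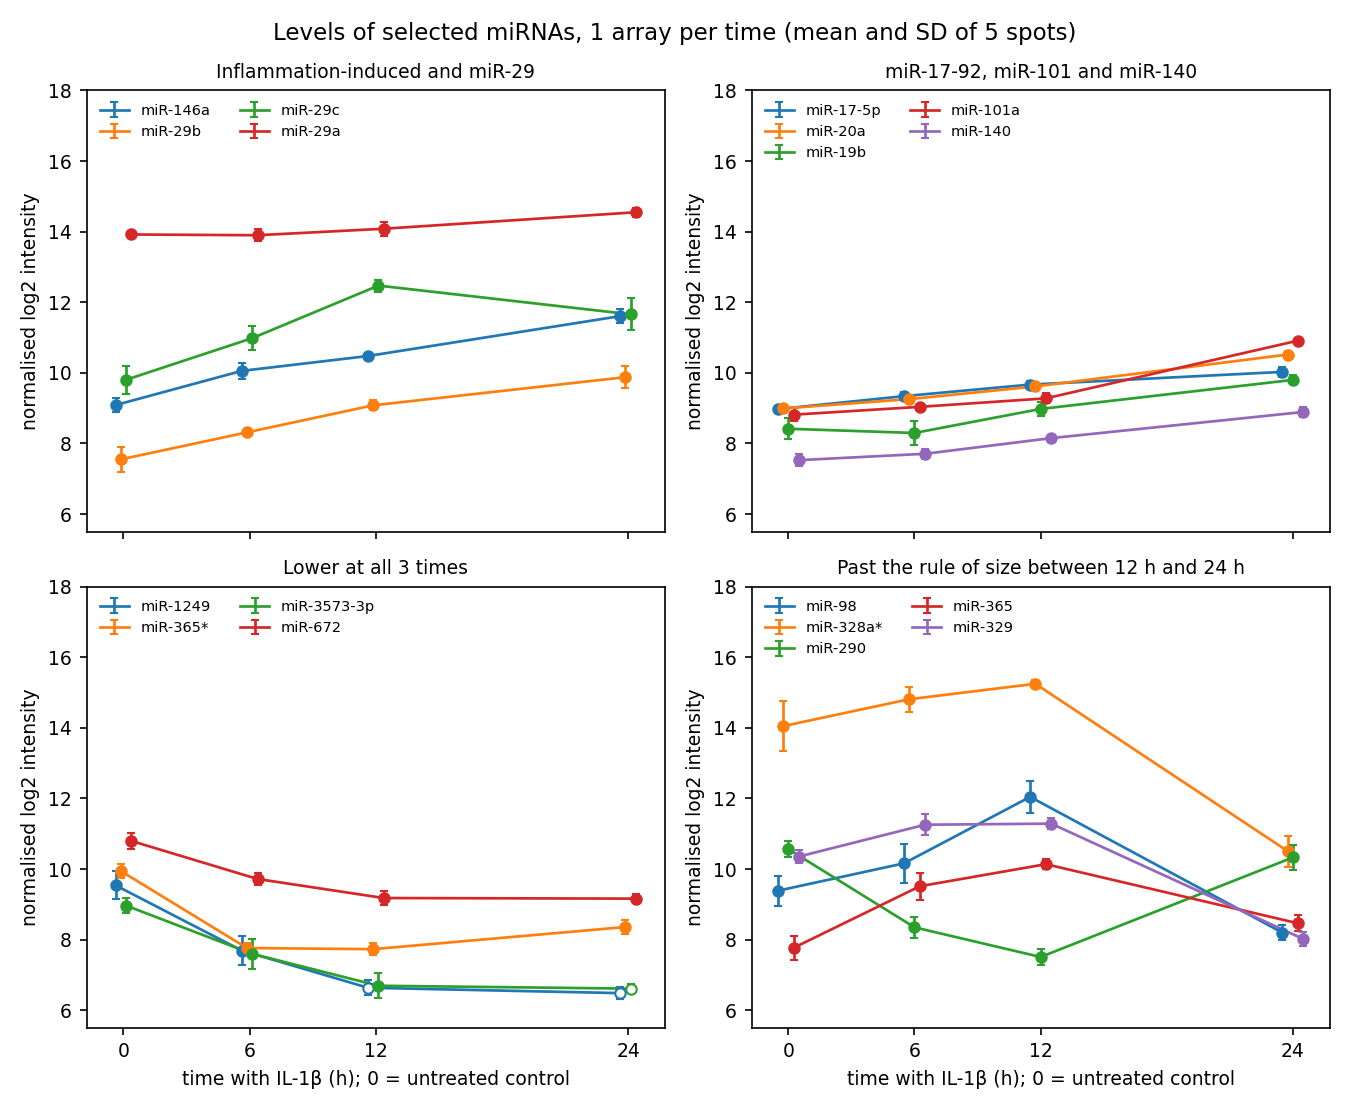
Mean log2 level (quantile-normalised intensity, y axis) in the control (0 h) and after 6, 12 and 24 h of IL-1β (x axis, hours) for selected miRNAs in 4 panels; error bars are the SD of 5 spots on 1 array, and open markers are levels that were not detected. miR-146a went from 9.09 in the control to 11.61 at 24 h, and miR-98 from 9.38 to 12.04 at 12 h and 8.20 at 24 h.

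**Figure D3:**
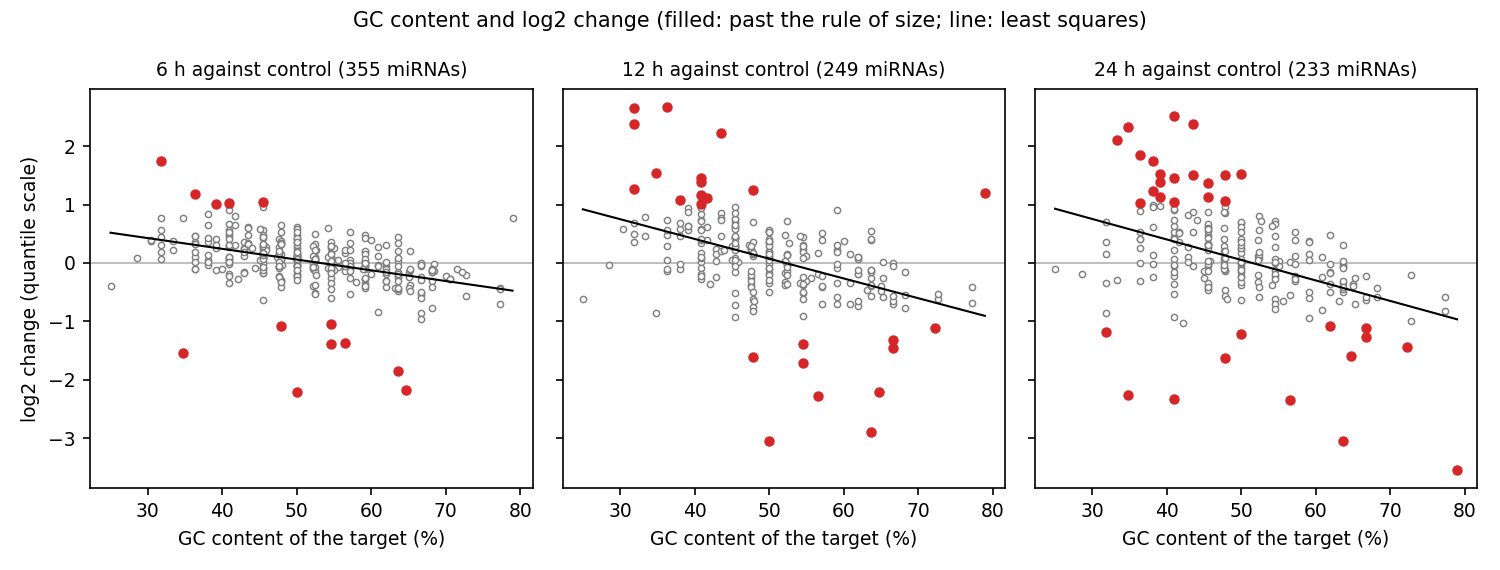
Log2 change against the control (y axis) by GC content of the miRNA (x axis, percent) at 6, 12 and 24 h; each point is a miRNA compared, filled where it passed the rule of size, and the line is the least-squares fit. The slope was -0.18, -0.34 and -0.35 per 10 percent GC.

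Only 6 miRNAs changed the same way at all 3 times on the quantile scale. miR-29c and miR-322, the rodent counterpart of human miR-424, were higher each time, and miR-1249, miR-365*, miR-3573-3p and miR-672 were lower each time. miR-322, undetected in the control, was at least 1.40-fold, 1.88-fold and 1.87-fold higher, and with undetected levels at the lowest detected one 5 of the 6 remained. All 3 comparisons share 1 control array, so that an odd value on it recurs at each time. Noise between arrays was not measured, so how many such miRNAs a shared control alone gives is not known. In 1000 simulations of unchanged arrays, noise was taken from the spread among the 3 treated arrays, which also holds changes over time. They asked only for a 2-fold change of one sign at all 3 times, without the detection filter or the spot-error rule. On average 3.79 of 357 miRNAs met this, and at most 11, against an average of 0.056 with the median spread in place of the root mean square. The observed count was 6 also without the filter, and 6 without the spot-error rule. Median scaling gave 2 higher and 17 lower, leaving out normalization 4 and 3, loess 1 and 3, and GC correction 0 and 5. Without the 12 h array in the normalization, 5 miRNAs changed the same way at both 6 h and 24 h, against 8 with it. Changes at 6 h and 12 h were correlated across miRNAs (r = 0.886) beside the 0.499 that a shared control gave in simulations with noise alike on all arrays. For 6 h and 24 h the values were 0.503 and 0.499, and for 12 h and 24 h 0.538 and 0.501. With noise alike on all arrays, the simulated value follows from the shared control whatever the data. It is therefore not a measured baseline, and nearness to it does not show that the shared control caused the correlation.

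The treated arrays were also compared with each other, which leaves out the control. From 6 h to 12 h, 5 of 355 miRNAs changed: miR-98 rose 3.69-fold (log2 1.88 ± 0.32), miR-494 3.09-fold (1.63 ± 0.28), miR-29c 2.81-fold (1.49 ± 0.17) and miR-665 2.25-fold (1.17 ± 0.20). miR-1249, chosen for mention after its values were seen, fell at least 2.08-fold. miR-98 and miR-29c are among the related probes that read higher on the 12 h array, and 3 changes remained without such probes. The split of 4 higher and 1 lower became 25 and 0 without normalization, 9 and 0 after centring, and 4 and 2 after median scaling.

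From 12 h to 24 h, 24 of 248 miRNAs changed, 11 higher and 13 lower. miR-290 rose 7.07-fold (2.82 ± 0.19), back towards its control level, and miR-101a 3.11-fold (1.64 ± 0.08). Other rises were those of miR-3593-3p 3.02-fold (1.59 ± 0.10), miR-101b 2.25-fold (1.17 ± 0.09) and miR-143, known from smooth muscle and other mesenchymal cells, 2.21-fold (1.15 ± 0.06). miR-328a* fell 26.8-fold (-4.74 ± 0.20), miR-98 14.4-fold (-3.85 ± 0.22) and miR-329 9.65-fold (-3.27 ± 0.11). let-7e fell 3.23-fold (-1.69 ± 0.14) and miR-365 3.20-fold (-1.68 ± 0.12). These changes did not run with GC content (r = -0.00019), whereas those from 6 h to 12 h did (r = -0.34). The 12 h array with its higher mismatch signal enters each of them. The split became 11 and 10 without related probes, 9 and 17 after loess, 7 and 22 after median scaling and 4 and 23 without normalization, and the call of miR-143 ended in 5 settings, at 0.54 to 0.89, and that of miR-101b without normalization (0.97).

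By the fixed lists, the inflammation-induced miRNAs had a median log2 change of 0.17, 0.15 and 0.51 at 6, 12 and 24 h over 8 members compared, positive under every scaling. At 24 h this median lay at the 98.7th percentile of random lists of like level, and miR-146a was the member that rose at 12 h and 24 h on the quantile scale. Of the others, miR-221 (0.85), miR-222 (0.81) and miR-31 (0.67) were positive at 24 h without passing, and miR-21 was at 0.25. miR-221 passed there after loess and median scaling, and miR-221, miR-222 and miR-31 all passed without normalization and after centring. The miR-29 family had medians of 0.77, 1.53 and 1.85 over 3 members, positive under every scaling, with miR-29c passing at 6 h and both miR-29b and miR-29c at 12 h and 24 h on the quantile scale. Both are related probes of the brighter miR-29a, 1 edit (miR-29c) and 4 edits (miR-29b) away, and on the 12 h array, with its higher mismatch signal, miR-29c read 1.15 above the mean of 6 h and 24 h and miR-29b -0.02. miR-29a was at 0.63 at 24 h, and passed without normalization. The 6 h median lay at the 98.6th percentile, against the 76.7th after loess, the 95.4th after GC correction and the 59.6th after median scaling, without normalization and after centring. At 12 h it lay at the 99.8th, against the 96.6th after loess and the 96.0th after median scaling, without normalization and after centring, and at 24 h at the 99.7th. The last 3 of these settings differ only by a constant within a comparison. Any list therefore has the same percentile under all 3 by construction, and they count as 1 alternative there. The miR-17-92 cluster and its paralogs had medians of 0.26, 0.51 and 0.88 over 9 members, and at 6 h the sign turned after loess (-0.0051) and median scaling (-0.07), with a median of 0.38 after centring. At 24 h 4 members rose (miR-17-5p, miR-19b, miR-20a and miR-20b-5p) and 5 did not pass on the quantile scale, at the 99.8th percentile. In sign, 7 members were positive and 2 negative, miR-92a (-0.014) and miR-25 (-0.11). miR-20b-5p and miR-18a are related probes of the brighter miR-20a, 2 and 4 edits away, so their values may not be separate from its signal. miR-20a passed under every scaling, but median scaling left only miR-19b beside it and GC correction only miR-20b-5p. With undetected members at their bound the medians were 0, 0.51 and 0.82 at 6, 12 and 24 h. The 6 h median of 0.26 thus rests on levels below detection.

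The let-7 family had medians of 0.20 and 0.22 at 6 h and 12 h over 8 members, which turned to -0.07 and -0.22 after GC correction. miR-98 and let-7e rose at 12 h on the quantile scale, and the call of let-7e ended after GC correction (0.79). miR-98 is a related probe, 2 edits from let-7a, and read 2.87 higher at 12 h than on the mean of 6 h and 24 h. The related probes are only those with a probe at least 4 times brighter, and let-7e and the other members are not among them. Whether those members read signals separate from each other was not examined. At 24 h the median was -0.35, at the 0.365th percentile, with miR-98 lower, 7 of the 8 members negative and 7 not past the rule. Without normalization this median was 0.29, which holds the shift of all changes on that scale, and -0.01 after centring, both at the 0.85th percentile, and in the authors' values -0.23, at the 8.35th, which no longer stood apart. The chondrocyte-enriched miRNAs had medians of -0.22, -0.26 and -0.07 over 5 members. The 6 h median lay at the 6.59th percentile, at the 1.98th in the authors' values and at the 50.1th after GC correction (-0.03). Their sign turned under centring at 6 h (0.26), at 12 h after GC correction (0.13), and at 24 h in 4 settings (0.0095 to 0.36), centring among them (0.20). Without normalization the medians were 0.32 at 12 h and 0.50 at 24 h, shifted with all changes; at 12 h centring left -0.08, at the 10.8th percentile either way. miR-140 went from 0.18 at 6 h to 0.62 at 12 h and rose at 24 h. Its opposite arm miR-140* was at -0.53, -0.70 and -0.31 and miR-455 at 0.14, 0.46 and 0.59. Regulators of cartilage matrix and proteases had medians of -0.10, -0.14 and 0.20, positive in place of negative without normalization (0.30 at 6 h and 0.84 at 12 h), after median scaling (0.17 and 0.09) and after centring (0.62 and 0.43), and at 12 h after loess (0.13). The 24 h median lay at the 91.8th percentile on the quantile scale, the 92.2th after GC correction and the 96.8th in the authors' values, but at the 98.2th after loess and the 98.1th after median scaling, without normalization and after centring. Of the 11 compared at 24 h on the quantile scale, miR-140 and miR-146a rose, miR-98 fell and 8 did not pass.

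The miR-30 family had medians of 0.32, 0.57 and 0.74 over 5 members, positive under every scaling, and no member passed on the quantile scale. Without normalization 1, 5 and 4 members passed at 6, 12 and 24 h, and after centring 2, 3 and 2. After loess and after median scaling miR-30b-5p alone passed, at 12 h. In the miR-15/16 family miR-322 was called higher at each time on the quantile scale, a call that ended after median scaling at all 3 times (0.24, 0.71 and 0.50), after loess, GC correction, centring and without normalization at 6 h, and after centring at 24 h. The family medians were -0.0088, 0.02 and 0.28, with the sign turned at 6 h under every scaling but GC correction (0.10 to 0.75) and at 12 h after GC correction (-0.29). The miR-23/27/24 clusters had medians of -0.22, -0.26 and 0.13 with no member past the rule on the quantile scale, at the 6.67th and 16.7th percentile at 6 h and 12 h. The places were the 0.80th and 0.97th after loess, the 0.50th and 1.07th without normalization, with or without centring, the 8.50th and 9.20th in the authors' values, and the 14.0th and 36.7th after GC correction. The medians were 0.06 and 0.33 without normalization and 0.38 and -0.08 after centring, so that the sign moved with the common shift while the percentile did not. The miR-181 family had medians of 0.27, -0.20 and -0.46 and no member past the rule under any scaling, with 0.66 at 12 h without normalization and 0.25 after centring. The 0.0088 at 24 h without normalization holds the common shift, and centring left -0.29. The 2 members of the p53-responsive miR-34 family that were compared had medians of 0.05, 0.07 and 0.78 and did not pass on the quantile scale; the values were -0.34 at 6 h and -0.37 at 12 h after median scaling, -0.21 and -0.18 after loess, -0.21 at 6 h without normalization, -0.08 and -0.13 in the authors' values, -0.03 and -0.04 after GC correction and, after centring, 0.11 at 6 h and -0.03 at 12 h. The mesenchymal and fibroblast miRNAs had medians of -0.09, -0.18 and 0.07, with miR-10b rising at 6 h, and the sign turned at 6 h and 12 h after median scaling (0.17 and 0.06), without normalization (0.30 and 0.80) and after centring (0.62 and 0.40), at 12 h after loess (0.11), and at 24 h after GC correction (-0.03) and in the authors' values (-0.0014).

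**Figure D4:**
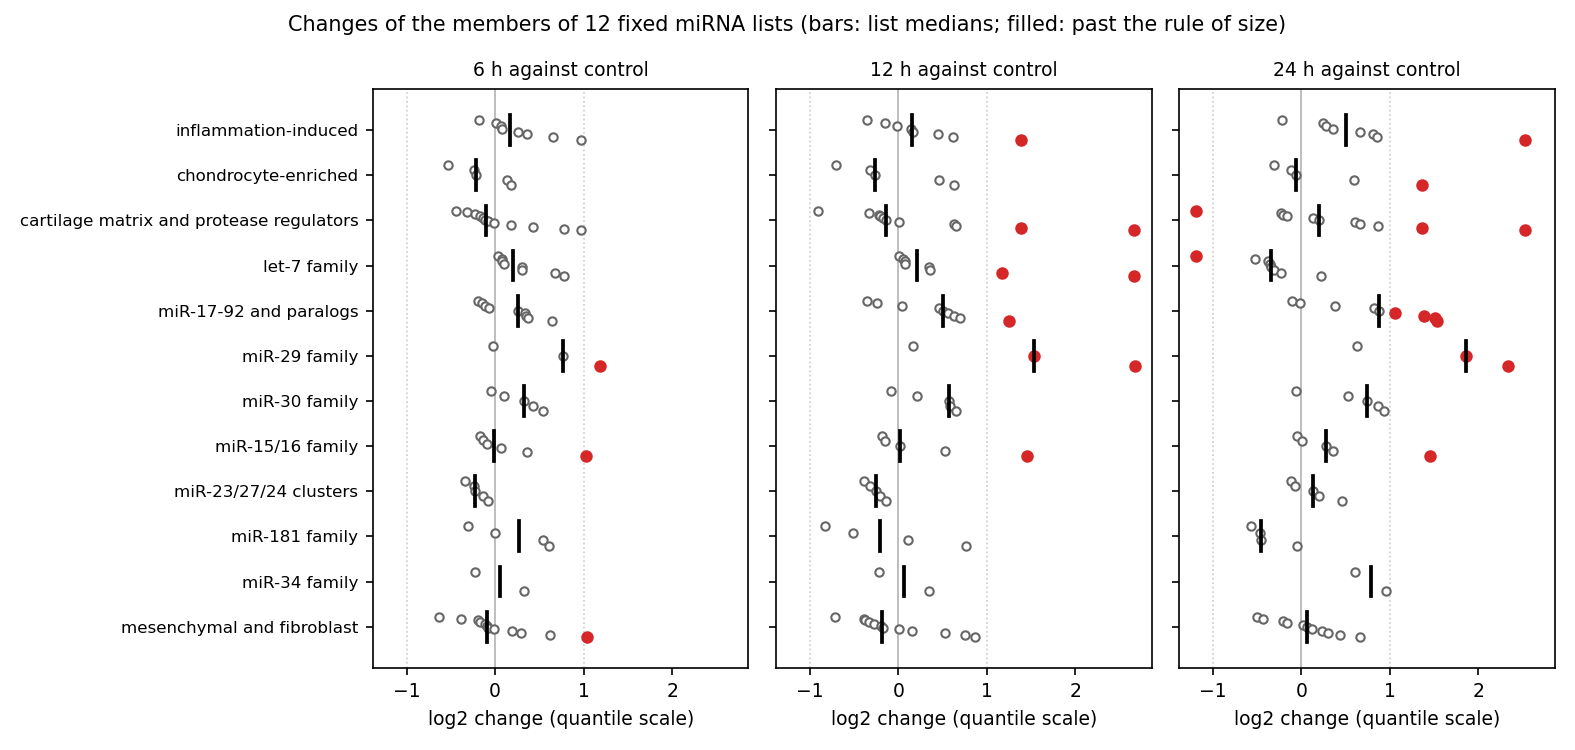
Log2 change against the control (x axis) of the members of 12 fixed miRNA lists (y axis) at 6, 12 and 24 h; each point is a miRNA, filled red where it passed the rule of size, black bars are list medians and dotted lines mark the 2-fold rule. On the quantile scale the miR-29 medians were 0.77, 1.53 and 1.85, positive under every scaling, and the let-7 median at 24 h was -0.35, which was 0.29 without normalization and -0.01 once those changes were centred.

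Several markers of other cell types that a cartilage culture could hold were not seen. Of the blood and macrophage markers, miR-142-3p, miR-223 and miR-451 were not detected on any array, and miR-150 had log2 changes of 0.26 at 6 h and 0.30 at 12 h. The liver marker miR-122 was not detected, and among epithelial markers miR-203 alone was compared, at 0.27 at 6 h. The endothelial marker miR-126 had 0.28 at 6 h and 0.70 at 12 h and was at least 1.98-fold higher at 24 h, a call that held in the authors' values and ended under the other scalings and GC correction, and miR-126* was not detected. The muscle marker miR-206 and the neural marker miR-128 were detected on all 4 arrays, the control among them. miR-206 was at -0.0063, -0.93 and -0.41 at 6, 12 and 24 h, with the 12 h value past the rule in the authors' values and after GC correction. miR-128 was at 0.42, 0.23 and 0.03.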

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

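The tests of hybridization stringency and of normalization for miR-98, and the comparison with the value that selection gives for the miRNAs that rose at 24 h, were chosen only after the result was seen.

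miR-98 stood out because its change turned with time, from a log2 rise of 2.66 at 12 h to -1.19 at 24 h; that difference was not tested, for want of replicates. Normalization between arrays is argued against as the cause of the 12 h rise, since its smallest value over 5 scalings was 2.64. Cross-hybridization may contribute: miR-98 is 2 edits from the brighter let-7a, and the 18 related probes as a set read higher at 12 h, at the 99.97th percentile of random lists of like level (99.9th without miR-98). These probes were chosen as dimmer on the control, 6 h and 24 h arrays, of which 6 h and 24 h are the reference for the excess. That choice can itself favour a higher value at 12 h, so the percentile does not decide. Lower stringency of the 12 h array is a candidate explanation as well. Only the 10 mismatched control probes above the empty spots on every array entered this comparison. Relative to matched partners, their 12 h signal was at least 2.96 times that on any other array (median of pairs). Other mismatched probes did not enter, and some stayed near background at 12 h, so the ratio does not cover them. An effect of IL-1β on miR-98 at 12 h stays open, and these tests do not cover its 24 h value.

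The miRNAs that rose at 24 h, among them miR-146a, miR-29b, miR-101a and miR-20a, were weighed as the set a biologist would follow first. From 6 h to 24 h, without the control, their median change was 1.19, and 11 of the 19 rose by 1 or more. Both meet the rule fixed beforehand against an odd control array. An odd control alone, with no noise on the 24 h array, would leave no such change. But choosing miRNAs on the 24 h array raises the median, to 0.75 with noise alike on all arrays, so the bound of 0.5 was too low. Of the 19, 16 exceed what that noise gives (median excess 0.29). Noise on the 24 h array only would give 1.505. Since noise was not measured, an odd control together with noise on the 24 h array cannot be told apart from the treatment. Nor can a trend with GC content be told apart for the set, since 63.2% of them (12 of 19) still passed after a linear correction, between the bounds fixed for either answer. Calls ended where the corrected change came under the 2-fold rule, as for miR-19b, from 1.39 ± 0.14 to 0.95. An IL-1β response of those that kept their call, such as miR-146a, may remain as a hypothesis. It needs replicate arrays, and untreated arrays of the same times to tell it from time in culture.

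The 4 miRNAs lower at all 3 times, miR-1249, miR-365*, miR-3573-3p and miR-672, were weighed against GC content and the higher background of the control array. After GC correction 100% of them still passed at all 3 times, so a linear trend with GC content is argued against as the whole cause. After plain subtraction of the empty-spot median 100% did as well. The main values were already corrected for background on each array, however, so this shows only that the falls hold under another correction. It cannot decide on the control array's higher background. An odd control value stays open, because all 3 comparisons use that array and noise between arrays was not measured. Time in culture stays open too, since untreated cells were not profiled at the later times.

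miR-328a* also turned with time, with a log2 change of 1.20 at 12 h and -3.54 at 24 h, a difference that was not tested. Among control spots outside the miRNA comparisons, those named Ctr03-3M05 read 5.29 times their control-array signal at 24 h. At 12 h, Ctr07-3M05 read 19.4 times, Ctr07-3M10 26.6 times and Ctr10-3M05 8.37 times their signal on the control array; the meaning of these names is read from their form and is not stated in the sources used here.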

How the results depend on the processing

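The GC correction, the normalization without the 12 h array, the removal of related probes, the centring and the lowest detected level for undetected miRNAs were tests chosen after seeing the data. No paired analysis was possible because each group is a single array, and leaving out replicates was not possible for the same reason. Of 76 single-miRNA results, 36 kept direction and call under every alternative that gave a value; of their 1240 values under alternatives, 1125 kept the call, 114 lost it and 1 reversed. Detection by all 5 spots gave 159, 263, 214 and 191 miRNAs in the control and at 6, 12 and 24 h, each within 1.5 times the main count. No background correction, cyclic loess, the authors' values, no filter, an offset of 16, the median of spots, no spot-error rule, GC correction and the lowest detected level left every count of changed miRNAs within 1.5 times.

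Where counts moved further, the cause was not tested except as said. Plain subtraction gave 20 at 6 h, 11 between 6 h and 12 h and 10 at all 3 times, against 13, 5 and 6. Median scaling gave 35, 42 and 53 at 6, 12 and 24 h and 19 at all 3 times, against 13, 24, 32 and 6. No normalization gave 25, 58 and 52 at 6, 12 and 24 h and 25 between 6 h and 12 h; centring those changes gave 27, 42, 50 and 9. Requiring detection on both arrays gave 18 at 24 h and 3 at all 3 times, by its construction. The 1.5-fold rule, looser by construction, gave 37, 73 and 79 at 6, 12 and 24 h, 18 between 6 h and 12 h, 62 between 12 h and 24 h and 18 at all 3 times. Leaving out related probes, which tests fewer, gave 3 between 6 h and 12 h. Without normalization miR-3584-5p reversed at 12 h, from -1.12 to 0.14, and the let-7 median at 24 h from -0.35 to 0.29. These values hold the shift of all changes on that scale, medians of 0.40 and 0.30, and centring on it left -0.26 and -0.01. Signal over background limits the dim miRNAs: the limit of detection was 151.3 units in the control and 54.2 at 6 h, so a miRNA seen at 6 h alone gives only a bound on its change.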

Other observations

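The test of hairpin arms was chosen before its result was seen, the runs without miR-365 and without miR-328a after it; the miRNAs of the next paragraph were chosen for mention after their values were seen.

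Beyond the miRNAs named by rule, several more changed from 12 h to 24 h of IL-1β. miR-146a rose by a further 1.13 on the log2 scale, the miR-17-92 paralog miR-106b by 1.06, miR-31 by 1.02 and miR-1224 by 1.1. The lower ones included miR-466b (-1.65), miR-32* (-1.35), miR-352 (-1.31), miR-10b (-1.18), miR-466d (-1.12) and miR-26b (-1.09). miR-352 and miR-26b are among the related probes and read higher at 12 h than on the mean of the 6 h and 24 h arrays, by 0.77 and 0.75. Against the control, further miRNAs were called at 24 h from levels below detection on 1 array, and as bounds none of them reached 2-fold. miR-221*, miR-495, miR-376b-3p and miR-186 were at least 1.76-fold, 1.59-fold, 1.54-fold and 1.49-fold higher. miR-341 and miR-1188-5p were at least 1.56-fold lower.

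A hypothesis was that both arms of one hairpin change together, as a shared precursor would have it. Over 83, 43 and 36 hairpins with both arms compared at 6, 12 and 24 h, the correlation of their changes was -0.17, -0.33 and 0.29, at the 6.36th, 2.09th and 96.5th percentile of random re-pairings. The arms had the same sign in 47, 24 and 17 hairpins. The values at 6 h and 12 h, which share a control array, rest on 1 hairpin: miR-365 rose and miR-365* fell at both times. Without it the correlations were 0.13, -0.03 and 0.33, at the 87.2th, 44.6th and 98.3th percentile. At 24 h the hairpin of miR-328a weighed most, and without it the correlation fell from 0.29 to 0.20. The test, which would have told against the hypothesis with the miR-365 hairpin in, thus decides neither way.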
